A study of Homo sapiens with 6 samples.

How the data were processed

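The data are 6 Affymetrix arrays of A549 cells, 3 with a lentiviral short hairpin against MRPL35 (KD) and 3 with a lentiviral control hairpin (NC). Per the labels' protocols, cells were grown in RPMI-1640 medium with 10% serum, total RNA was extracted with Trizol, and biotin-labelled cRNA was made from 6 ug of it. Samples were grouped and numbered by their titles. The source name of NC replicates 2 and 3 carries a different cell line number from that in their characteristics, which give A549 for all NC samples, and they were used as A549.

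The values used are the authors' deposited table of 49395 probe sets, used here as log2 probe-set values. The log base is not written in the table and was taken from the range of the values, which reach 14.3 with array medians between 5.49 and 5.55. How the authors summarised and normalized the probes is not given in the sources used here, so it is unknown how far that step compressed fold changes. The sorted values of the arrays were close but not identical. Between-array normalization sets what counts as unchanged, so all changes are relative to the bulk of genes, whose median log2 change was -0.018. Scanner files were not used here, so background was not measured per probe set and dim values are given as they stand.

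Probe sets were named from the platform annotation: 45278 had 1 gene symbol, 1333 several and 2682 none, and 102 were control probe sets. Of the 45278, 45208 had a gene identifier in the RefSeq table of assembly GRCh38.p14, which changed 0 symbols. No coordinates were taken from that table. Each of 18244 genes was represented by the probe set with exactly 1 symbol and the highest mean over the 6 arrays, a choice that affects the 11825 genes with several probe sets. No filter on dim genes was applied. Control probe sets served only to look at RNA quality.

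Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with the group as the only term, and p-values were adjusted by Benjamini-Hochberg over the 18244 genes with a threshold of 0.05. The fit had 4 residual and 4.67 prior degrees of freedom. Fold counts used an absolute log2 change of at least 1. The 48 gene lists were pathways and 8 sets of cell type markers, with 1070 distinct members measured of 1143, and were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 48 lists. Figures were drawn with matplotlib 3.10.9.

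The design, the gene lists, the alternatives and the rule for named genes were set before the data were examined. The rule named MRPL35, then the 12 largest rises and 12 largest falls with an adjusted p under 0.05, with all KD arrays beyond all NC arrays, and with the higher group's mean at or above the median of gene means, 6.21. It then named up to 4 members of each list with the largest changes under the same conditions, or the member with the smallest p where none passed. Genes named outside this rule are said to be so.

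The steps were tested on simulated values drawn independently for each gene around its NC mean, with the spread fitted for that gene. Of 66 genes given a log2 change of 0.5, 44 were recovered (66.7%), and all 67 at a change of 1 and all 67 at 2, while 12 of 18044 unchanged genes were called in the simulation of KD against NC over 18244 genes. Camera recovered 6 of 6 lists shifted by 0.3 and called 0 of 42 others. These were random lists of uncorrelated genes, whereas the real lists had estimated correlations of up to 0.42 (complex I). The simulation therefore does not give camera's rate of false calls on the real lists. The alternatives were quantile normalization, median centring, eBayes with trend and robust fitting, array weights, the replicate number as a block, the mean of a gene's probe sets, leaving out probe sets with x or s suffixes (which can hybridise to several transcripts), leaving out genes below the 40th percentile of mean level, leaving out each array, a treat test against 0.2, a 1.5-fold threshold, and camera on ranks. The alternative pseudocounts planned for linear values did not apply.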

Results

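Gene expression was measured in A549 cells, an established human lung adenocarcinoma line, after lentiviral delivery of a short hairpin RNA against MRPL35 (group KD, 3 samples) or of a control hairpin (group NC, 3 samples). MRPL35 encodes a protein of the large subunit of the mitochondrial ribosome, which translates the few proteins encoded in mitochondrial DNA. The comparison addresses what loss of MRPL35 does to division and death of non-small-cell lung cancer cells. Each sample was hybridised to 1 Affymetrix array with 49395 probe sets, from which 18244 genes were tested, and the number of arrays limits the precision. The labels do not say whether the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Arrays of one group correlated at 0.997 to 0.998 in KD and 0.994 to 0.998 in NC (Pearson's r across genes, which are not independent replicates), against 0.976 to 0.980 between the groups. The first principal component carried 79.0% of the variance and separated KD from NC, and the next carried 11.8% and set NC replicate 2 apart from the other 5 arrays. The difference between the 3' and 5' ACTB control probe sets, a sign of RNA integrity, was 0.63 ± 0.044 in KD and 0.58 ± 0.082 in NC (log2, mean ± SD, n = 3 each), and that for GAPDH was 0.086 ± 0.035 in KD and 0.012 ± 0.050 in NC.

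MRPL35 itself was lower in every KD array than in every NC array. Its brightest probe set read 6.49, 6.44 and 6.56 in KD replicates 1 to 3 and 8.16, 8.05 and 8.36 in NC replicates 1 to 3 on the log2 scale. The gene fell by 1.69 on the log2 scale with a standard error of 0.096, which is 3.23-fold lower (limma, adjusted p = 3.77e-06) and leaves 30.9% of the control signal. Of its other probe sets, tested over all probe sets, the 2 bright ones changed by -1.98 and -1.37 and the dim one by -0.42 (adjusted p = 0.0320), so that 4 of 4 fell.

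**Figure D1:**
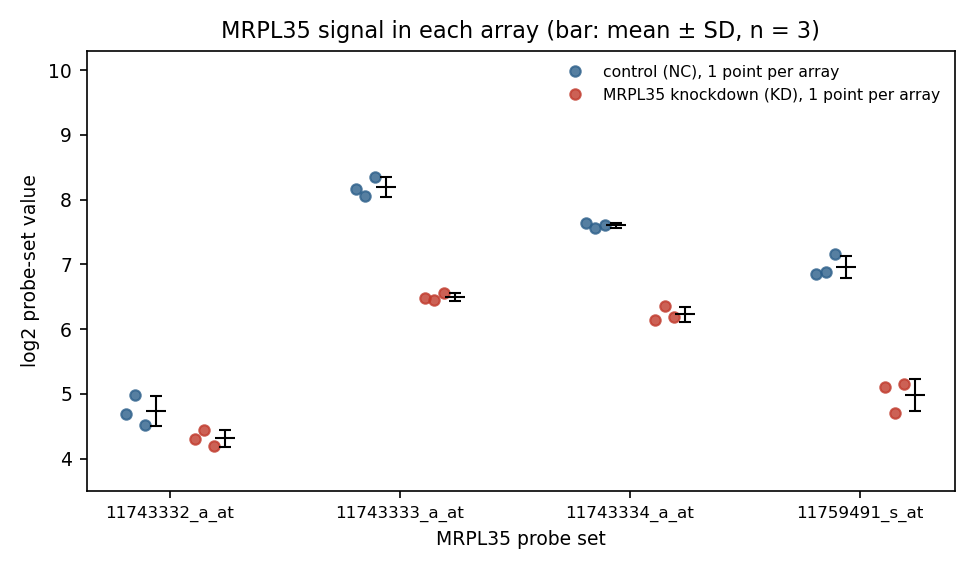
Log2 value of the 4 MRPL35 probe sets (horizontal axis) in each array, with 1 point per array, blue for control (NC) and red for knockdown (KD), and the mean ± SD of 3 arrays as a bar. At the probe set that stands for the gene, the KD arrays lie between 6.44 and 6.56 and the NC arrays between 8.05 and 8.36.

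The knockdown cells expressed 3207 genes at a higher and 2903 at a lower level than the control cells, which together make 33.5% of the genes tested (limma, adjusted p under 0.05). At least 2-fold changes were counted for 414 genes upwards and 564 downwards. The 12 largest falls, by the rule for named genes, were led by SDHD, the small membrane anchor subunit of succinate dehydrogenase, which was 7.48-fold lower. BCAT1, the cytosolic branched-chain aminotransferase, was 7.13-fold lower, and SPCS1, a subunit of the signal peptidase complex, 6.45-fold lower. The other falls were in genes of DNA replication and chromosome segregation. POLE2 (7.06-fold lower), GINS3 (6.82-fold), RRM2 (6.41-fold) and MCM10 (5.55-fold) act in DNA replication or in making its nucleotides, and MND1 (6.37-fold) acts in homologous recombination. CENPH (6.67-fold lower), SKA1 (5.48-fold), ASPM (5.48-fold) and DLGAP5 (5.39-fold) act at the centromere or the mitotic spindle.

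The 12 largest rises were of mixed kinds. FAM228B was 8.36-fold higher, CLIC3, of the chloride intracellular channel family, 8.07-fold, and VTN, the adhesion glycoprotein vitronectin, 6.59-fold. IFIT1 (7.05-fold higher) and TRIM22 (5.92-fold) are interferon-induced antiviral genes, and TP53INP1 (5.22-fold) is a target of the tumour suppressor p53. XDH (2.46 on the log2 scale) encodes the enzyme that makes uric acid, ABCA12 (5.44-fold) a lipid transporter, NEFL (5.39-fold) the light neurofilament chain and FBXO2 (5.18-fold) an F-box protein that binds glycoproteins. SCARNA14 (6.57-fold higher) and SNORA12 (2.46 on the log2 scale) are small RNAs that guide RNA modification. Whether their probe sets read these small RNAs or longer transcripts that contain them was not tested. Standard errors of these 24 log2 changes lay between 0.073 (NEFL) and 0.14 (GINS3), and adjusted p between 7.83e-07 (IFIT1) and 2.36e-06 (TP53INP1). A second, dim probe set of TP53INP1 changed by 0.13 and 1 of SPCS1 by -0.26, and neither passed the test. Of 5 probe sets for BCAT1, 1 dim one changed by -0.30 without passing. The second, dim probe set of SCARNA14 rose by 0.81 (limma adjusted p = 0.00138). CENPH, CLIC3, GINS3, IFIT1, MND1, POLE2 and SNORA12 rest on a single probe set each, and the values of SDHD, FAM228B, NEFL, CENPH, RRM2 and DLGAP5 on probe sets that can hybridise to more than 1 transcript by their suffix.

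**Figure D2:**
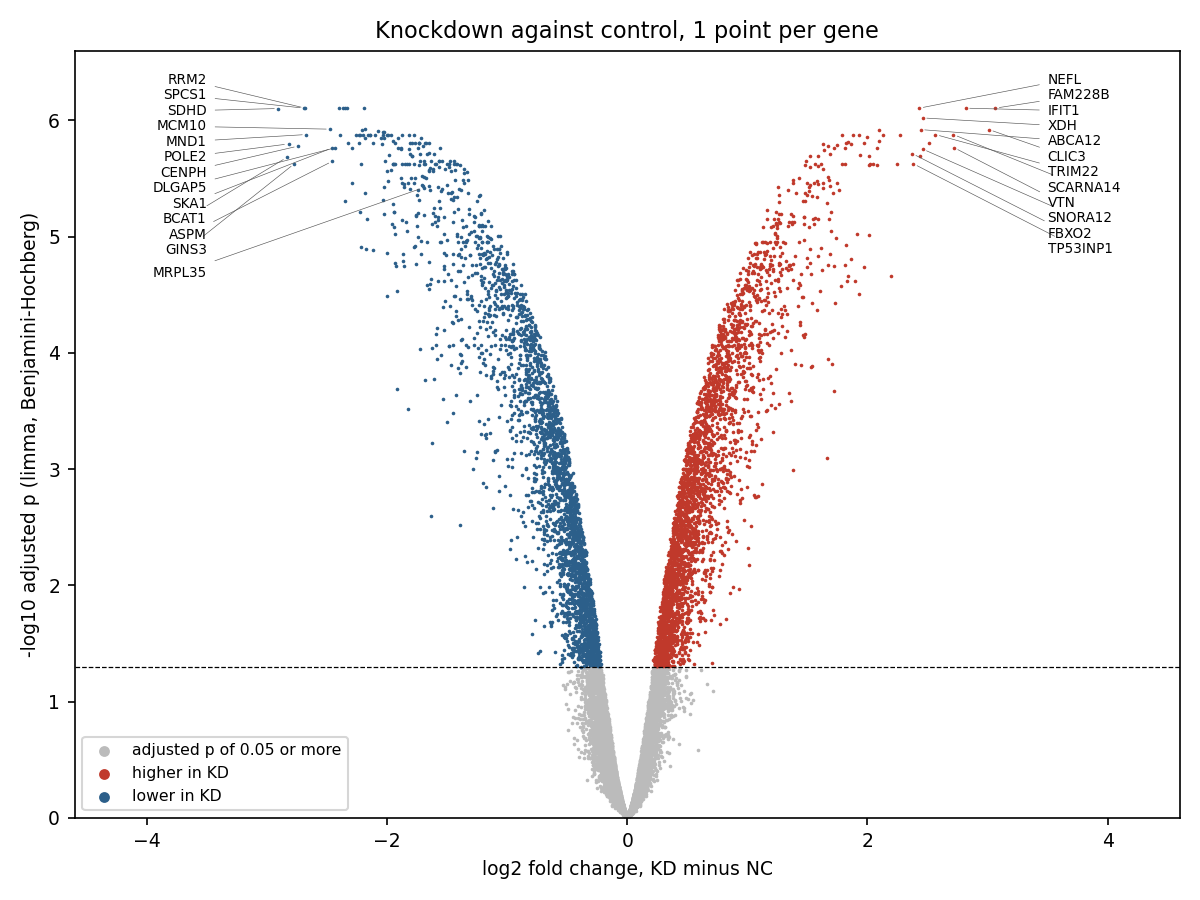
Log2 fold change (KD minus NC, horizontal axis) against -log10 of the limma adjusted p (vertical axis), with 1 point per gene for 18244 genes and the dashed line at an adjusted p of 0.05. The 3207 genes in red were higher and the 2903 in blue lower in KD, and MRPL35 and the 12 largest rises and falls carry their names, from FAM228B at 3.06 to SDHD at -2.90.

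Of 48 gene lists fixed before the data were examined, camera with its preset correlation called 21 at an adjusted p under 0.05, 11 of them higher and 10 lower in KD. With a correlation estimated from these arrays camera called 0 of the 48, with 6 at an unadjusted p under 0.05. That setting also tests on the fit's 4 residual degrees of freedom, which by itself raises p. For NF-kB targets the estimated correlation was -0.012, below the preset 0.01, yet the camera adjusted p went from 0.0603 to 0.246. A call lost in that setting can therefore come from the fewer degrees of freedom, from correlation between genes, or from both. The estimated correlation was 0.31 for the large and 0.32 for the small mitoribosomal subunit and 0.42 for complex I. Correlation can weigh heavily in such lists, and these sources were not told apart. The fry test, which asks only whether a list's own genes move one way, called 35. Changes below are given as log2 KD minus NC ± standard error (limma, n = 3 per group), and members are said to rise or fall where their adjusted p over all genes was under 0.05.

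The lists of G2/M and of G1/S genes fell almost throughout, and most repair genes fell with them. Of 44 measured genes of G2/M and mitosis 43 fell and 1 rose, with a median change of -1.85, a 3.62-fold lower level. The rise numbered 0 without any 1 of the KD replicates, NC replicate 1 or NC replicate 2. Examples are ASPM (-2.45 ± 0.12), DLGAP5 (-2.43 ± 0.11), TTK, a kinase of the spindle checkpoint (-2.39 ± 0.099), and KIF20A, a kinesin of late mitosis (-2.37 ± 0.075). All 44 measured genes of G1/S and DNA replication fell, with a median of -1.48, and POLE2 (-2.82 ± 0.13), GINS3 (-2.77 ± 0.14), RRM2 (-2.68 ± 0.076) and MCM10 (-2.47 ± 0.088) changed most. Among 24 DNA damage repair genes 18 fell and 0 rose, with a median of -0.58; they include BLM, a helicase (-2.03 ± 0.13), BRCA1 (-1.94 ± 0.12), EXO1, an exonuclease (-1.79 ± 0.079), and RAD51AP1 (-1.69 ± 0.19). Adjusted over the list alone the counts were the same for the cell cycle lists, and 19 repair genes fell. These lists were called lower by camera (adjusted p = 7.43e-32 for G2/M, 3.69e-28 for G1/S and 1.59e-08 for repair). With an estimated correlation the adjusted p was 0.201 for each of the 3. The mean level of the G2/M list in NC replicate 2 lay at -0.12 relative to the mean of the NC arrays, against -1.71 to -1.79 in the KD arrays.

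The list of G1 cyclins, their kinases and inhibitors moved both ways, with 5 of 19 genes higher and 10 lower, the same counts adjusted over the list alone, and did not pass camera (adjusted p = 0.175). CDC25A, the phosphatase that activates CDK2 (-1.29 ± 0.097), CDK6 (-1.22 ± 0.097) and MYC (-1.15 ± 0.093) fell, while CDKN1A, the CDK inhibitor p21, rose (1.04 ± 0.081). Histone genes showed 4 of 17 lower and 1 higher, also when adjusted over the list alone, among them H2BC12 (-1.87 ± 0.10) and H2AX (-1.31 ± 0.080), and the list did not pass (camera adjusted p = 0.328). Without NC replicate 2 the rises numbered 2.

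Targets of p53 rose as a group. Of 27 measured genes 21 rose and 1 fell, with a median change of 0.78, or 1.71-fold, and 23 rose and 1 fell adjusted over the list alone (camera adjusted p = 2.87e-11). The adjusted p with an estimated correlation was 0.246. The fall numbered 0 without KD replicate 1, KD replicate 3, NC replicate 1 or NC replicate 3. TP53INP1 (2.38 ± 0.12), ZMAT3 (1.75 ± 0.097), TP53I3 (1.59 ± 0.10) and SPATA18 (1.28 ± 0.11) rose most. Genes that promote apoptosis went in both directions, with 9 of 26 higher and 5 lower (10 and 6 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.198). The BH3-only gene BIK (1.44 ± 0.12), the death receptors FAS (1.27 ± 0.074) and TNFRSF10A (1.06 ± 0.099) rose. The TNF receptor TNFRSF1A fell (-1.04 ± 0.076), a call that was lost with cross-hybridising probe sets left out. Of 13 genes that oppose apoptosis, 1 rose and 1 fell, also adjusted over the list alone: BAG1 (0.91 ± 0.073) and BIRC5, survivin, which is also a mitotic gene (-1.42 ± 0.083). Without NC replicate 2 the falls numbered 2. That list had a camera adjusted p of 0.955, and its median of 0.021 and mean of -0.031 differed in sign.

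**Figure D3:**
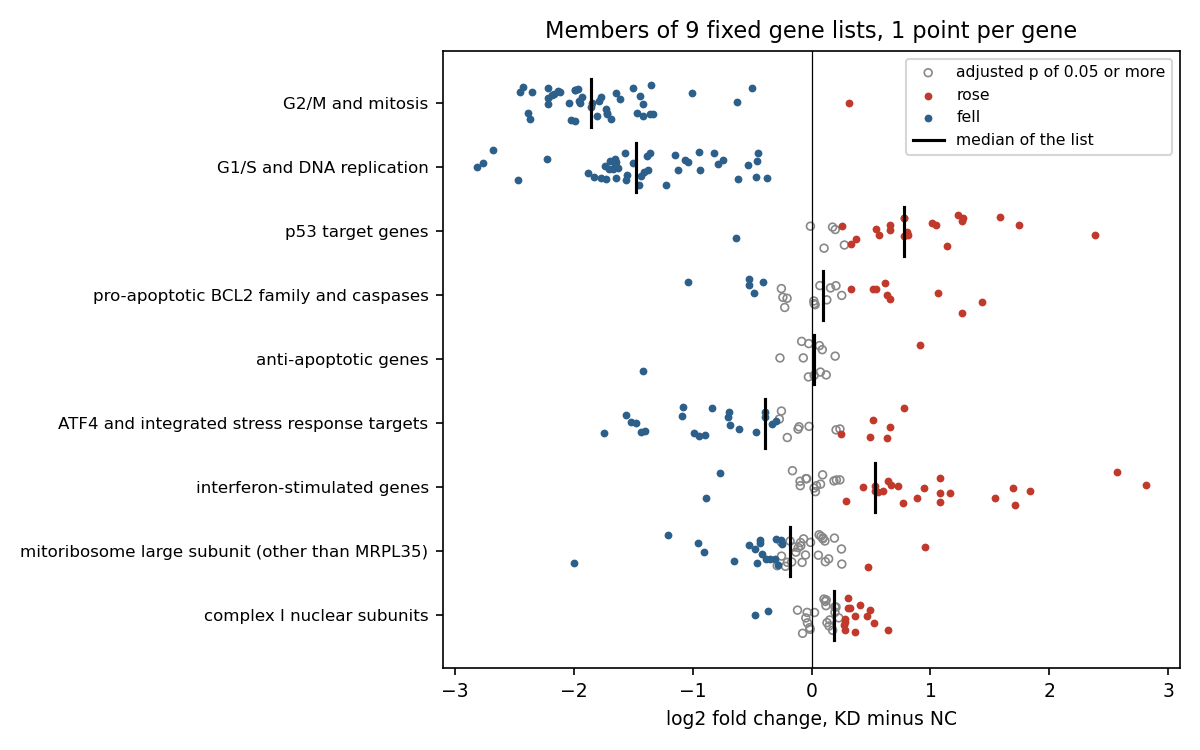
Log2 fold change (KD minus NC, horizontal axis) of each measured gene of 9 fixed lists, with 1 point per gene, filled red where the gene rose, filled blue where it fell, open where it did not pass, and the median as a black line. The 44 G1/S genes all lie left of 0, the 27 p53 targets have a median of 0.78, and the ATF4 targets spread over both sides.

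Lists of genes that supply growth were called lower as well. In the list of MYC targets and ribosome biogenesis 26 of 29 genes fell and 0 rose, with a median of -0.67 (camera adjusted p = 4.50e-12, and adjusted p = 0.201 with an estimated correlation). These include TCOF1 (-1.57 ± 0.094), PA2G4 (-1.18 ± 0.077), and the nucleolar genes NOLC1 (-1.15 ± 0.082) and DKC1 (-1.13 ± 0.082). Serine, one-carbon and nucleotide synthesis had 16 of 24 genes lower and 1 higher, with a median of -0.70 (camera adjusted p = 8.10e-08, and adjusted p = 0.246 with an estimated correlation). Besides RRM2 these were led by the purine synthesis genes IMPDH1 (-1.94 ± 0.13) and PFAS (-1.82 ± 0.076) and by PHGDH, the entry enzyme of serine synthesis (-1.48 ± 0.075). Cytosolic ribosomal protein genes moved little, with 6 of 33 lower and 0 higher and a median of -0.13 (camera adjusted p = 0.0114, and adjusted p = 0.290 with an estimated correlation). RPL38 (-0.61 ± 0.078) and RPL10A (-0.55 ± 0.082) fell most. Adjusted over the list alone the counts were the same for the ribosome lists, and 17 fell and 2 rose for nucleotide synthesis. Of the control probe sets for ribosomal RNA, the 28S 5' one read lower in KD, at 11.70 ± 0.027 against 12.43 ± 0.11 in NC (log2, mean ± SD, n = 3 each), and the 28S middle one changed by -0.65. The dim 28S 3' one (-0.12, limma adjusted p = 0.440) and the 3 for 18S (-0.042, -0.055 and -0.085) did not pass.

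Lists of mitochondrial ribosome genes other than the target were called lower, with most members not passing. In the large subunit 18 of 47 genes fell, 2 rose and 27 did not pass, with a median of -0.18 (camera adjusted p = 0.00361, and adjusted p = 0.555 with an estimated correlation). MRPL42 (3.99-fold lower), MRPL46 (-1.21 ± 0.079) and MRPL10 (-0.96 ± 0.086) fell, and MRPL33 rose (0.95 ± 0.12). In the small subunit 11 of 31 genes fell and 1 rose, with a median of -0.13, led by MRPS27 (-1.23 ± 0.14) and MRPS2 (-1.01 ± 0.085). Its camera adjusted p of 0.0192 became 0.0567 without NC replicate 1 and 0.0764 without NC replicate 3, and 0.555 with an estimated correlation. Its camera alternatives ranged from 0.00160 to 0.555. Mitochondrial translation and RNA factors had 15 of 31 genes lower and 1 higher, with a median of -0.25 (camera adjusted p = 0.000325, and adjusted p = 0.246 with an estimated correlation). Among these are the mitochondrial aminoacyl-tRNA synthetases MARS2 (-1.17 ± 0.19), LARS2 (-0.66 ± 0.078) and AARS2 (-0.55 ± 0.087). Adjusted over the list alone, 19 large-subunit genes fell and 3 rose, 11 small-subunit genes fell and 1 rose, and 17 factors fell and 1 rose. The rise in the small subunit numbered 0 without KD replicate 2, KD replicate 3 or NC replicate 1 and 2 without NC replicate 3, and that among the factors 0 without KD replicate 2, KD replicate 3 or NC replicate 2.

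Among nuclear genes of the respiratory chain, the complex I list was called higher and the others did not pass. Of 36 complex I genes 14 rose and 2 fell (15 and 2 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.00361, and adjusted p = 0.555 with an estimated correlation). NDUFB2 (0.52 ± 0.072) and NDUFS8 (0.49 ± 0.080) rose and NDUFA9 fell (-0.48 ± 0.083). The number of rising complex I genes dropped to 7 without KD replicate 2, 8 without KD replicate 3 and 9 without NC replicate 1, and the falls to 1 without KD replicate 1. Complexes III and IV had 10 of 27 genes higher and 4 lower (12 and 4 adjusted over the list alone) and did not pass camera (adjusted p = 0.162), with COX15 at -1.01 ± 0.10 and SURF1 at 0.44 ± 0.079, both of cytochrome oxidase assembly. That list passed with trend and robust fitting (0.0439), within a range of 0.0439 to 0.555 over its camera alternatives. ATP synthase had 4 of 16 higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.162), led by its inhibitor ATP5IF1 (0.65 ± 0.080). The rises there numbered 2 without KD replicate 2, KD replicate 3 or NC replicate 3. The tricarboxylic acid cycle had 7 of 18 genes higher and 3 lower (9 and 4 adjusted over the list alone) and did not pass (camera adjusted p = 0.252). It held SDHD (-2.90 ± 0.097), IDH3G (0.83 ± 0.086) and PDHB (0.69 ± 0.099), and its median of 0.13 and mean of -0.0058 differed in sign.

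Mitochondrial chaperones and proteases had 1 of 16 genes higher and 5 lower, the same adjusted over the list alone (camera adjusted p = 0.262), among them DNAJA3 (-0.48 ± 0.097) and the protease OMA1 (-0.42 ± 0.095). The falls there numbered 3 without KD replicate 2 or 3, and the rise 0 without KD replicate 1 and 2 without NC replicate 3. Genes of mitochondrial dynamics, mitophagy and biogenesis went both ways, with 6 of 25 higher and 9 lower (7 and 9 adjusted over the list alone), and did not pass (camera adjusted p = 0.846). The mitophagy genes BNIP3L (1.25 ± 0.086) and PINK1 (1.04 ± 0.086) rose. The fusion gene MFN2 (-1.04 ± 0.084) and PPARGC1A, a coactivator of mitochondrial biogenesis (-1.04 ± 0.092), fell.

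Targets of ATF4, the transcription factor of the integrated stress response, were mostly lower. Of 35 genes 21 fell and 6 rose (23 and 6 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 3.89e-05, and adjusted p = 0.246 with an estimated correlation). The falls were largest in the amino acid transporter SLC7A5 (-1.74 ± 0.10), asparagine synthetase ASNS (-1.57 ± 0.078), STC2 (-1.52 ± 0.080) and PHGDH (-1.48 ± 0.075). The endoplasmic reticulum unfolded protein response had 9 of 22 genes higher and 3 lower, also adjusted over the list alone, and did not pass (camera adjusted p = 0.0520), with the chaperone genes DNAJB9 at 0.97 ± 0.086 and CALR at 0.79 ± 0.16. It passed without NC replicate 1 (0.0207) or NC replicate 3 (0.0382), with trend and robust fitting (0.0311), with the mean of a gene's probe sets (0.0174) and with camera on ranks (0.0444), within a range of 0.0174 to 0.378 over its camera alternatives. The heat shock list had 2 of 15 genes higher and 5 lower (2 and 7 adjusted over the list alone) and did not pass (camera adjusted p = 0.175). CRYAB rose (1.86 ± 0.084) and CHORDC1 fell (-1.39 ± 0.14) there.

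Interferon-stimulated genes rose. Of 37 measured genes 22 rose and 2 fell, the same adjusted over the list alone, with a median of 0.53, or 1.45-fold (camera adjusted p = 2.44e-07, and adjusted p = 0.201 with an estimated correlation). IFIT1 (2.82 ± 0.080), TRIM22 (2.57 ± 0.10), the transcription factor IRF9 (1.84 ± 0.080) and ISG15 (1.71 ± 0.099) rose most. Of 14 genes of MHC class I and antigen processing 7 rose and 1 fell (8 and 1 adjusted over the list alone). The peptide transporter TAP1 (1.26 ± 0.076), the proteasome subunit PSMB10 (0.89 ± 0.085) and B2M (0.58 ± 0.081) rose, and TAPBP fell (-0.69 ± 0.080). That list's camera adjusted p of 0.0158 became 0.246 with an estimated correlation, 0.160 with cross-hybridising probe sets left out and 0.0604 with dim genes left out, within a range of 0.00961 to 0.246 over its camera alternatives. NF-kB targets had 10 of 24 genes higher and 2 lower (11 and 2 adjusted over the list alone) and did not pass (camera adjusted p = 0.0603), with the chemokine CXCL8 at 1.20 ± 0.097 and SOD2 at 1.11 ± 0.092. It passed without KD replicate 2 (0.0370) or NC replicate 1 (0.0438), within a range of 0.0370 to 0.246 over its camera alternatives. Its falls numbered 1 without any 1 of the KD replicates or NC replicate 3.

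**Figure D4:**
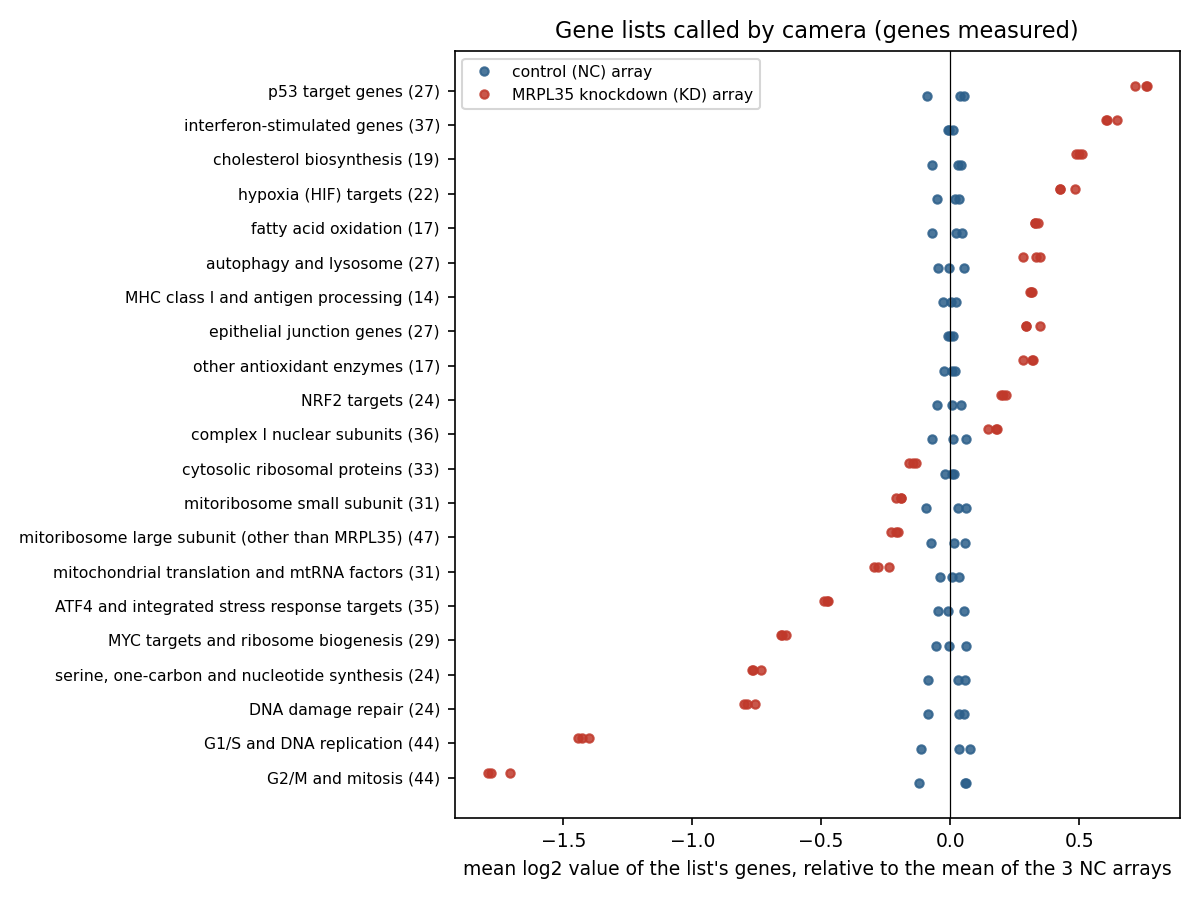
Mean log2 value of each list's measured genes in each array relative to the mean of the 3 NC arrays (horizontal axis), for the 21 lists called by camera, with 1 point per array, red for KD and blue for NC, and the number of genes measured in brackets. The KD arrays lie from -1.79 for G2/M to 0.76 for p53 targets, apart from the NC arrays in every list shown.

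Several metabolic lists were higher. Cholesterol biosynthesis had 12 of 19 genes higher and 1 lower (13 and 1 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 2.85e-05, and adjusted p = 0.246 with an estimated correlation). STARD4, a sterol carrier (1.47 ± 0.093), INSIG1, a regulator of sterol sensing (1.38 ± 0.11), and HMGCS1, an enzyme of the pathway (1.20 ± 0.089), rose. Fatty acid oxidation had 10 of 17 higher and 0 lower, also adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.00165, and adjusted p = 0.355 with an estimated correlation), including CPT1A, which controls entry of fatty acids into mitochondria (0.86 ± 0.082). Fatty acid synthesis and desaturation had 8 of 15 higher and 3 lower, also adjusted over the list alone, and did not pass (camera adjusted p = 0.175), with the elongase ELOVL6 at 1.79 ± 0.092 and ACLY at -0.81 ± 0.075. It passed with cross-hybridising probe sets left out (0.0207) and with the mean of a gene's probe sets (0.0369), within a range of 0.0207 to 0.555 over its camera alternatives. Hypoxia targets had 10 of 22 higher and 2 lower (11 and 2 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.000939, and adjusted p = 0.246 with an estimated correlation), led by STC1 (2.01 ± 0.098) and NDRG1 (1.40 ± 0.081). Glycolysis had 9 of 21 higher and 2 lower, also adjusted over the list alone, and did not pass (camera adjusted p = 0.0520), with ENO2 at 1.63 ± 0.092 and PFKFB3 at -0.94 ± 0.074. It passed without NC replicate 3 (0.0382), with trend and robust fitting (0.0439), with the mean of a gene's probe sets (0.0333), with cross-hybridising probe sets left out (0.00561) and with camera on ranks (0.0444), within a range of 0.00561 to 0.545 over its camera alternatives.

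NRF2 targets had 11 of 24 genes higher and 2 lower (13 and 2 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.00933, and adjusted p = 0.355 with an estimated correlation). AKR1C1 (1.13 ± 0.078) and ALDH3A1 (1.01 ± 0.077) rose, while HMOX1, heme oxygenase, fell (-1.82 ± 0.092). Other antioxidant enzymes had 7 of 17 higher and 2 lower, also adjusted over the list alone, with a median of 0.16; SOD2 (1.11 ± 0.092) and GPX1 (0.82 ± 0.079) rose. The camera adjusted p of 0.0158 became 0.0803 with dim genes left out and 0.246 with an estimated correlation, over camera alternatives that ranged from 0.00788 to 0.246, and the 2 falls numbered 0 without any 1 of the KD replicates and 1 without any 1 of the NC replicates. Autophagy and lysosome genes had 15 of 27 higher and 3 lower (15 and 4 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 0.000939, and adjusted p = 0.246 with an estimated correlation). GABARAPL1, of the autophagosome (1.25 ± 0.084), and the lysosomal proteases CTSB (1.07 ± 0.075) and CTSD (0.98 ± 0.098) rose. Proteasome genes had 1 of 29 higher and 2 lower, 1 and 1 adjusted over the list alone (camera adjusted p = 0.846), with PSMD8 at 0.39 ± 0.077. The falls there numbered 1 without any 1 of the KD replicates or NC replicate 3. PI3K-AKT-FOXO targets had 8 of 18 higher and 2 lower (9 and 3 adjusted over the list alone) and did not pass (camera adjusted p = 0.0520), with CCNG2 at 1.17 ± 0.13 and KLF2 at 1.02 ± 0.090. That list passed without KD replicate 2 (0.0378), KD replicate 3 (0.0385), NC replicate 1 (0.0287) or NC replicate 3 (0.0305). It also passed with median centring (0.0408), trend and robust fitting (0.0460), the replicate number as a block (0.0420) and the mean of a gene's probe sets (0.0229). Its camera alternatives ranged from 0.0229 to 0.378. Its falls numbered 0 without KD replicate 3 or NC replicate 1, and 1 without KD replicate 1, KD replicate 2 or NC replicate 3.

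The list of epithelial junction genes was called higher, with 10 of 27 genes higher, 2 lower and 15 not passing (11 and 2 adjusted over the list alone), and a median of 0.21 (camera adjusted p = 0.0113, and adjusted p = 0.246 with an estimated correlation). LAMB3, a laminin chain of the basement membrane (1.97 ± 0.088), CDH1, E-cadherin (1.31 ± 0.12), and the desmosome genes JUP (1.25 ± 0.080) and DSP (1.21 ± 0.17) rose. Mesenchymal and matrix genes had 8 of 29 higher and 5 lower, also adjusted over the list alone, and did not pass (camera adjusted p = 0.438), with PLAU, urokinase, at 1.13 ± 0.074 and COL6A1 at 0.90 ± 0.13. Targets of TGF-beta and YAP had 5 of 22 higher and 7 lower, also adjusted over the list alone (camera adjusted p = 0.175), with CRIM1 at -2.20 ± 0.088, ID2 at -1.76 ± 0.13 and LATS2 at 1.01 ± 0.084. The rises there numbered 2 without KD replicate 1, KD replicate 3 or NC replicate 1, and 3 without KD replicate 2. The list passed without NC replicate 2 (0.0480), within a range of 0.0480 to 0.555 over its camera alternatives. Immediate early and MAPK feedback genes had 8 of 24 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.175), with the phosphatase genes DUSP5 at 1.11 ± 0.088 and DUSP4 at 0.69 ± 0.093.

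Markers of other cell types that a culture could hold were tested in 8 lists, of which camera called 0. Alveolar type II and club cell markers had 1 of 15 genes higher, ABCA3 (1.14 ± 0.084), and 0 lower (camera adjusted p = 0.667), and mucin and goblet markers 4 of 12 higher, led by MUC5B (1.04 ± 0.12), and 2 lower (0.667). Squamous and basal markers had 2 of 11 higher, among them KRT15 (1.05 ± 0.088), and 0 lower (camera adjusted p = 0.246). Fibroblast markers had 4 of 15 higher and 1 lower (0.667), leukocyte markers 1 of 14 higher, CD14 (0.60 ± 0.11), and 0 lower (0.675), and endothelial markers 1 of 13 lower, ESAM (-0.33 ± 0.094), and 0 higher (0.502). Embryonic kidney markers, typical of lentivirus packaging cells, had 3 of 12 higher and 1 lower (camera adjusted p = 0.344), with NEFL at 2.43 ± 0.073 and INA at 0.79 ± 0.079. Neuroendocrine markers had 1 of 10 higher, ENO2 (1.63 ± 0.092), and 0 lower (0.993). Adjusted over the list alone the counts were the same except that 0 endothelial markers fell and 2 embryonic kidney markers fell. With 1 array left out, the fall of a fibroblast marker was lost in every case but KD replicate 3, and that of ESAM without KD replicate 2, KD replicate 3 or NC replicate 1. Without NC replicate 2, 3 alveolar markers rose and 2 embryonic kidney markers fell. Median, mean and test differed in sign for the fibroblast list (median -0.013, mean 0.059, test up) and the neuroendocrine list (median -0.066, mean 0.091, test down).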

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

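The splits of the samples were set as a test before the data were examined, while the tests below of SDHD, of the interferon-stimulated genes and of the ATF4 targets were chosen after the results were seen. Probe sets outside the comparison of genes carried a difference between the groups. Of 2682 probe sets with no gene symbol 371 were higher and 348 lower in KD (limma, adjusted p under 0.05), which is 26.8% of them. Of 1333 probe sets with several gene symbols 209 were higher and 145 lower, or 26.6%. Both shares lie below the 33.5% called among the 18244 genes tested, each gene read at its brightest probe set. These probe sets were singled out because they show a signal in data that the report's comparisons leave aside. What they measure was not identified.

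The 5' control probe set for 28S ribosomal RNA also lies outside the comparison of genes and differed between the groups, by -0.73 (KD minus NC, log2, limma adjusted p = 0.00023). The middle 28S probe set changed by -0.65 and the dim 3' one by -0.12 (adjusted p = 0.440). The 18S probe sets changed by -0.042, -0.055 and -0.085, and did not pass. The cause was not tested.

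Splitting the 6 arrays into 3 and 3 gives 10 splits, too few for a share under 0.05. The split into KD and NC called 6110 genes, 978 of them at least 2-fold, and 21 gene lists by camera with its preset correlation. It was the 1 of the 10 splits to reach each of these values. The highest of the other splits was 0 genes and 0 at least 2-fold by limma, the only tool run on the splits for genes, with up to 1130 genes at an unadjusted p under 0.05. For the lists the highest of the other splits was 19. Each other split has KD and NC arrays on both sides, so the difference between KD and NC enters its residual spread. Few or no genes are then called whenever KD and NC differ, and the lists called can hold part of that difference. Neither count tells what chance alone would give.

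SDHD (-2.90), BCAT1 (-2.83) and SPCS1 (-2.69) fell more than the hairpin's target, MRPL35 (-1.69), and are not genes of cell division. A single aberrant probe set is argued against for SDHD, as 4 of its 4 other probe sets fell too, although 2 of these hold identical values and all carry suffixes of possible cross-hybridisation. A joint fall of the complex's subunits that takes in SDHA and SDHC is also argued against. Their median change was 0.223, with SDHA at 0.41 (limma adjusted p = 0.00297) and SDHC at 0.036. The subunit SDHB was not among the genes tested, so a fall shared with it stays open. In contrast, SDHAF2, an assembly factor of the complex, changed by -1.57 ± 0.078. SDHA, SDHC and SDHAF2 were chosen after their values were seen. The hairpin acting directly on other transcripts cannot be told apart from a response to the loss of MRPL35, because 1 hairpin was compared with 1 control and its sequence was not used here. As a description only, 141 genes fell more than MRPL35, of which 44 are on the G1/S, G2/M or DNA repair lists.

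Interferon-stimulated genes rose, 22 of 37 with a median of 0.53. Leukocytes in the KD cultures are argued against, as 1 of 14 of their markers rose (CD14), while the brightest, TYROBP and CD68, read 7.06 and 7.03 in KD against 7.01 and 6.88 in NC, and the labels describe no sort that would remove such cells. Interferon made by the cells stays open: the larger change of IFNB1 and IFNL1 was -0.0713, but their group means of 2.94 to 3.61 lie far below the median gene level of 6.21, where a rise might not be seen, and these 2 genes were chosen after the result was seen. A response to the MRPL35 hairpin or to a different dose of virus goes with the group in every array and was not tested. A response to the loss of MRPL35 remains open in the same way.

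Targets of ATF4 fell on balance, 21 of 35, and ATF4 itself changed by -0.70 ± 0.077 (chosen after its values were seen). The 6 that rose were SESN2 (0.78), GDF15 (0.66), NUPR1 (0.63), DDIT4 (0.52), VLDLR (0.49) and SARS1 (0.25), named after their values were seen. The members shared with the serine, one-carbon and nucleotide list do not account for the falls alone, since 16 of the other 30 fell and 6 rose, with a median of -0.317 (camera p = 0.000467 with the preset and 0.124 with an estimated correlation). Slower growth with less demand for amino acids and lower ATF4 activity after loss of MRPL35 are both open and were not tested.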

How the results depend on the processing

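All alternatives were set before the data were examined, and no others were added. MRPL35 stayed lower and past the threshold under each alternative for which it was read out, which leaves aside the treat test and the 1.5-fold threshold. Its log2 changes ran from -1.76 to -1.37, and from -1.76 to -1.61 with 1 array left out. With 1 array left out, the genes higher in KD numbered 2612 to 3467, those lower 2343 to 3279, those at least 2-fold higher 366 to 463 and lower 524 to 620. Lists called numbered 21 to 23. Of the 6110 genes called, 4916 to 5886 were called again, and 6025 with quantile normalization, 5881 with median centring and 5315 with the mean of a gene's probe sets.

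The count of genes fell to 1931 higher and 1826 lower with a treat test against 0.2, which asks for larger changes, and a 1.5-fold threshold gave 1417 higher and 1415 lower. Camera with an estimated correlation called 0 lists (6 at an unadjusted p under 0.05), against 35 by fry, whose test does not compare a list with other genes. The mean correlation of arrays within minus between groups, 0.0186, was 0.0207 with cross-hybridising probe sets left out, 0.0578 with dim genes left out, and 0.0179 to 0.0195 with 1 array left out. For these similarity values the cause was not tested.

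Whether replicate numbers pair the samples is undecided with so few arrays. Deviations from the group means correlated at 0.25, 0.26 and -0.096 between KD and NC arrays of the same number. KD replicate 2 correlated best with NC replicate 2, but KD replicate 1 correlated better with NC replicate 3 (0.29) and KD replicate 3 with NC replicate 2 (0.15). With the number as a block 3262 genes were higher and 3014 lower (5932 of them among the 6110), 414 and 564 changed at least 2-fold up and down, 22 lists were called (PI3K-AKT-FOXO targets gained the call, 0.0420), and MRPL35 changed by -1.69 (adjusted p = 9.23e-06).

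The direction given by the list test, camera or fry, changed in 6 lists that neither of them called. Their medians lie near 0 and did not always change sign with the test. The cause was not tested. For anti-apoptotic genes the median was -0.024 with array weights, -0.0018 with dim genes left out, 0.021 with fry and -0.020 to 0.057 with 1 array left out. For proteasome genes it was -0.052 to 0.0040 with 1 array left out. Mitochondrial dynamics had -0.028 with the mean of probe sets, 0.0096 without cross-hybridising probe sets and -0.074 to 0.0038 with 1 array left out. Leukocyte markers had -0.031 without cross-hybridising probe sets and -0.059 to 0.072 with 1 array left out, and endothelial markers -0.12 to 0.027. Neuroendocrine markers had -0.066 with trend and robust fitting and with fry, -0.022 with array weights, -0.065 without cross-hybridising probe sets, -0.040 without dim genes and -0.096 to 0.0074 with 1 array left out. Without cross-hybridising probe sets another probe set stood for CS (0.031) and UQCRB (-0.0053), which turned both.

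Of the other values of the named genes under the alternatives, 2428 kept their direction and call and 42 lost the call. The rule picked these genes for their changes in the same arrays, so their kept calls say little about other genes. Of all 6110 genes called, 4916 to 5886 were called again with 1 array left out. For lists 727 values kept direction and call, 38 gained a call and 26 lost it, 21 of these with the estimated correlation. The others were the small mitoribosomal subunit without NC replicate 1 (0.0567) or NC replicate 3 (0.0764), antioxidant enzymes without dim genes (0.0803), and MHC class I without dim genes (0.0604) or cross-hybridising probe sets (0.160), all as adjusted p. Pseudocounts were not run, since the values were already logarithms. Background was not measured here, so how far it limits what dim genes could show is unknown.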

Other observations

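All tests in this part were chosen after the results were seen, and the genes were chosen after their values were seen. Among genes that rose at least 2-fold were several of the complement system and its regulation: VTN (2.72), CFI (2.52, at a dim level of 5.63 in KD), C3 (2.13) and C1S (3.99-fold higher). Of 23 other complement genes 8 rose and 0 fell. Their median was 0.0327, but several were dim in both groups, such as C9 (2.82 in KD, 2.79 in NC) and C6 (3.36 and 3.40). A change there might not be seen. Camera called the 23 genes higher (p = 0.00601, adjusted over the 3 lists of this part 0.0180, and p = 0.112 with an estimated correlation). The 8 that rose all read above the median gene level of 6.21 in KD. So did CD55 (0.21) and C4BPB (-0.061), which did not pass. CFD (1.58), C1R (1.58), CFB (1.47), CD46 (1.21) and C1RL (1.09) rose most. A candidate explanation is that part of the complement genes rose together in KD, which rests on the preset correlation and on data in which it was first seen.

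LAMB3 (1.97) and ITGB4 (2.04), which act together in hemidesmosomes, rose in KD. The 4 other measured genes of that structure and of laminin-332 had a median of 0.121, and limma's camera did not call them. The camera p over these genes was 0.736. ITGA6 (0.58) and DST (0.43) rose while CD151 fell (-0.46), and so few genes leave a joint rise undecided.

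SNORA12 and SCARNA14 were among the 12 largest rises. The 63 other small nucleolar and Cajal body RNAs had a median of -0.0903 (camera p = 0.0303, adjusted 0.0454, and p = 0.231 with an estimated correlation), and 1 rose, SNORA21 (0.90), while 10 fell. Of the 63, 58 lie below the median gene level of 6.21, where a small rise might not be seen, and of the 5 at or above it 3 fell and 0 rose. A level below the median did not hide large rises, as SCARNA14 read 3.90 and SNORA12 5.69 in NC (log2 means). These values argue against a joint rise as large as that of SNORA12 and SCARNA14, for members that read at similar levels in NC. A smaller rise among the dimmest stays open, and whether the probe sets read the small RNAs themselves was not tested.

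A gain or loss of a whole chromosome between the groups is argued against. With 18172 genes placed on 23 chromosomes, the chromosome medians lay between -0.0457 and 0.0254, and camera with the preset correlation called 0 of the 23, with 0 at an unadjusted p under 0.05.

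Among single genes, COX3, which is encoded in mitochondrial DNA, changed by 0.11 ± 0.10 (limma adjusted p = 0.486). The proliferation marker MKI67 changed by -1.65 ± 0.078.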
